A study of Mus musculus with 6 samples.

How the data were processed

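Single-cell RNA was measured in 6 libraries of mouse blastoids, embryo-like structures grown for 5 days from expanded potential stem cells of the E14 line, with 5 cells seeded per microwell. Libraries were made with the Chromium 3' chemistry, version 3.1, per the labels' protocols. Per the file headers, the authors ran Cell Ranger 6.0.1, and each deposited matrix holds raw counts of unique molecular identifiers (UMIs) per gene and cell barcode. Seurat and the genome build mm10 are named in the submitters' processing notes, and what Seurat was used for is not given in the sources used here. No deposited annotation of cells was used. The titles give each library a grade (Good, Average or Bad) and a library set (CellTag or E14_EP). Each set holds 1 library of every grade, so each grade has 2 libraries. The protocol describes a sorting of the structures by morphology into types I to III, and no label says which grade is which type. Replicate 1 is the CellTag library and replicate 2 the E14_EP library. The labels do not say whether the sets came from separate cultures, so p-values measure only the spread between these libraries.

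The deposited matrices held 95693 barcodes and between 94934538 and 171863240 UMIs per library. Barcodes were kept with at least 1000 UMIs, at least 500 genes and at most 15% mitochondrial UMIs, which 78827 passed. Doublet scores were computed per library with Scrublet in scanpy 1.11.5. Its automatic threshold marked 0, 869 and 1437 cells in the CellTag Good, Average and Bad libraries and 0, 1 and 0 in the E14_EP libraries. It had therefore not worked in 4 of 6 libraries. Calls by Scrublet had been planned. In place of the automatic threshold, the highest-scoring cells were removed in every library at an expected rate of 0.8% per 1000 cells, a choice made after the scores were seen. This removed 8614 cells and left 70213, with between 79101476 and 152804790 UMIs per library. Intervals on shares of cells are exact Clopper-Pearson intervals at 95% and cover counting error only. A count of 0 was given the limit of 3 cells of the total.

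Cells were normalised to the same total, log-transformed and reduced to 40 principal components of 3000 variable genes. Leiden clusters (leidenalg 0.10.2) were computed at resolution 1 on 20 neighbours per cell, without batch correction, which gave 18 clusters. Marker lists of 12 cell types and 16 pathway lists were fixed before the data were examined, as were the tests, the covariates, the rule for named genes and most alternatives. A cluster was named after the list with the largest share of markers raised at least 1.5-fold over all other cells and detected in at least 10% of its cells, with 3 such markers as the minimum. Clusters stayed unnamed if cells were below 1/3 of their library's median UMI count with no own marker among the 10 leading genes. They also stayed unnamed if at least 2 leading genes were ribosomal RNA, nuclear or mitochondrial transcripts, or if markers of another list outnumbered their own there. The thresholds of the naming rule were set after the clusters were seen. The names are rebuilt here and can differ from those of the study.

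UMI counts were summed per library over all kept cells, and per library and class. Cells were not treated as replicates. Sums were tested with edgeR 4.0.16 (TMM factors, filterByExpr, glmQLFit and glmQLFTest) in R 4.3.3, with library set as a covariate for grades and grade as a covariate for sets. All 6 libraries entered each fit and shared 1 estimate of the spread. The Benjamini-Hochberg adjusted p had to be under 0.05. A fit with robust estimation of the prior was looked at first, before the default settings, which the planned test names, were adopted, and it is kept as an alternative. Standard errors were derived from the log2 fold change and the F statistic. Gene lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry from limma 3.58.1 beside it, adjusted over 28 lists. Within a class, the test was run where every library had at least 50 cells, which held for 5 classes. The named classes and clusters 5 and 8 made a family of 8 shares, adjusted together, and other clusters were tested without adjustment. Shares were tested by an exact permutation, counting both directions, of the grades within each set on the trend from Bad over Average to Good, with 36 arrangements and a smallest possible p of 0.0556. Differences given per set are on the log2 scale of CPM, the count scaled by the library's summed count, plus 1.

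Named genes for each comparison of grades were those past the threshold with the same direction in both sets, at least 20 CPM in the grade where they were higher, and a symbol that was not a predicted gene, a ribosomal protein gene or a mitochondrial gene. The 12 with the largest rise and the 12 with the largest fall were taken. Where fewer than 6 passed, the 6 with the smallest p were given as values. For each list, up to 4 members with the smallest p were added, and within a class the 6 largest in each direction. Some genes that the rule takes are not reported here. Positions come from the GENCODE annotation of mm10, in which 32235 of the 32285 gene identifiers were found.

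The procedure was tested on simulated data for Good against Bad with 18005 genes tested. It recovered 77 of 100 genes changed by 1 on the log2 scale and 100 of 100 changed by 2, with 0 wrong directions and 16 false calls. Simulated genes were independent and had the same set effect in every grade, so grade effects that differ between the sets are not covered. Replicate libraries of a grade differed far beyond sampling noise, with a chi-square per degree of freedom of at least 221. The pairing by library set comes from the titles. Deviations from the grade means correlated across genes at 0.827, 0.789 and 0.526 between the 3 libraries of a set.

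Alternatives were DESeq2 1.42.0, upper-quartile factors, no filter on genes, no covariate, all deposited barcodes, doublets kept, other clusterings, other filters on cells and leaving out each library in turn. DESeq2 gave 3234 of the 18533 genes no adjusted p between Good and Bad. Those added after the data were seen were robust estimation of the prior, at least 3000 UMIs per cell for the counts of genes, Scrublet's automatic threshold, cells of named classes alone, naming by marker counts alone, cluster 15 counted as epiblast-like, and cluster 6 tested alone. Python 3.11.15 was used with scipy 1.17.1.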

Results

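Mouse blastoids are structures that resemble the blastocyst and are assembled from stem cells in culture. Here they came from expanded potential stem cells of the E14 line, grown in microwells with FGF4, BMP4, a GSK3 inhibitor and an inhibitor of Activin and Nodal receptors. They were picked by hand on day 5. The 6 single-cell libraries carried 3 morphological grades, Good, Average and Bad, with 2 libraries per grade. One library of each grade belonged to a set titled CellTag and the other to a set titled E14_EP. The design asks how the cellular makeup and expression of the structures differ with their morphology.

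After filtering, the CellTag set held 7944 Good, 14750 Average and 12802 Bad cells, and the E14_EP set held 10971, 11212 and 12534. Depth was uneven. Median UMIs per cell were 16532, 8471 and 10292 in the CellTag Good, Average and Bad libraries and 14295, 3854 and 5144 in the E14_EP libraries. Barcodes above 15% mitochondrial UMIs made up 23.1% of the E14_EP Average library and 24.8% of the E14_EP Bad library, against between 5.13% and 7.16% in the other 4. Shares of cells in the E14_EP Average and Bad libraries therefore rest on shallower cells.

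Of 18 clusters, 10 could be named. Epiblast-like cells (clusters 0, 13 and 17) expressed 18 of 20 naive pluripotency markers in each of clusters 0 and 13, among them Pou5f1, Nanog and Sox2. Cluster 17 held 62 cells with a median of 36944.5 UMIs, so unremoved doublets remain open there. Formative-epiblast-like cells (cluster 2) expressed Otx2, Pou3f1, Dnmt3b, Pim2 and Sfrp2, and T and Nodal were among their leading genes. Primitive-endoderm-like cells fell into cluster 4, led by Rbp4 and apolipoprotein genes, cluster 6, led by Glipr2, Tfec and Gata6, and cluster 7, led by Spink1 and Cubn. Trophectoderm-like cells (cluster 10) expressed 14 of 22 trophectoderm markers, including Gata2, Gata3, Rhox6, Rhox9 and Plac1. Cdx2, Elf5, Tead4 and Tfap2a were not among its raised markers, while Cdx2 was raised in the unnamed clusters 8 and 11. Cluster 1 was 2C-like and expressed Zscan4c, Zscan4d and Usp17l genes, whose near-identical copies can share reads. Blood-like cells (cluster 16, 186 cells) as a whole expressed Hbb-bh1, Hba-x, Gata1 and Tal1.

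The other 8 clusters stayed unnamed. Cluster 5 raised 15 of 25 primitive endoderm markers, but its leading genes were Pitx1, Igfbp1, Myl3 and Flt1. Cluster 8 raised 10 of 22 trophectoderm markers, but it was led by Hoxaas3, Wnt6, Tgfb2, Msx1 and Fgf8. Each of these clusters had 0 of its own markers and 1 of another list among its 10 leading genes. The remaining 6 were shallow or led by nuclear, ribosomal RNA or mitochondrial transcripts. Unnamed clusters together held 58.0%, 41.4% and 26.5% of CellTag Good, Average and Bad cells. In the E14_EP set they held 27.3%, 53.7% and 36.9%.

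Trophectoderm-like cells, as cluster 10, were more frequent in Bad than in Good structures in both library sets. They made up 1.34% ± 0.438 of Good, 2.48% ± 0.797 of Average and 8.05% ± 0.0582 of Bad cells (SD, n = 2 each). The share was 4.91 times higher in Bad than in Good in the CellTag set and 7.78 times higher in the E14_EP set. The order was the same in both sets, and the exact permutation test gave p = 0.0556, the smallest that 36 arrangements allow. Adjusted over the 8 classes and clusters tested, p was 0.222, so no share could pass the threshold. With clusters named by marker counts alone, which adds cluster 8, the CellTag shares were 8.89%, 18.6% and 17.5% in Good, Average and Bad, so the sets no longer shared an order (exact permutation p = 0.167), and Bad over Good was 1.97 and 4.57 in the CellTag and E14_EP sets. At Leiden resolution 2 the CellTag shares of Good and Bad were 11.5% and 20.6%, and Bad over Good was 1.80 and 5.02.

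Primitive-endoderm-like cells as a class, as named here without cluster 5, did not follow the grades. They made up 36.9% ± 4.39 of Good, 25.3% ± 5.45 of Average and 34.3% ± 4.67 of Bad cells (SD, n = 2 each; exact permutation p = 0.778). Its clusters took different parts. Cluster 6, with raised Gata6, Lama1, Lamb1 and Lamc1, held 3.75%, 5.45% and 15.5% of CellTag Good, Average and Bad cells and 7.18%, 7.18% and 23.6% of E14_EP cells. Cluster 4, with the secreted visceral products Rbp4, Ttr and Apoa1, held 29.6%, 21.99% and 14.2% of the CellTag cells and at most 1.00% of an E14_EP library. Cluster 7, with the endocytic receptor genes Cubn, Amn and Lrp2, held 31.8%, 13.96% and 13.9% of E14_EP cells and at most 1.68% of a CellTag library. These genes did not fully separate the clusters, since Cubn, Amn and Lrp2 were also raised in cluster 6 and Lama1 in clusters 5 and 7. Ttr and Apoa1 were also raised in cluster 7, Ttr and Rbp4 in cluster 5, and Amn in clusters 4 and 5. Few cluster 4 cells in the E14_EP set therefore do not mean that Ttr and Apoa1 were absent there. Exact permutation p was 0.111 for cluster 6, 0.0556 for cluster 4 and 0.500 for cluster 7, computed outside the 8 classes and clusters of the main family and not adjusted. Unnamed cluster 5 held 27.4%, 17.7% and 5.01% of CellTag Good, Average and Bad cells and 0.957%, 0.196% and 0.120% of E14_EP cells (exact permutation p = 0.0556, adjusted p = 0.222). The Good minus Bad difference of the class was 2.64 percentage points on average and depended on the clustering, at 14.3 with clusters named by marker counts alone, which adds cluster 5, and at -2.82 after centring within library sets.

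Epiblast-like cells, as named here, had opposite orders over the grades in the library sets. In the CellTag set they made up 4.22% (95% interval 3.79 to 4.68) of Good, 15.5% of Average and 19.3% (18.6 to 20.0) of Bad cells. E14_EP libraries held 21.5% (20.7 to 22.3), 14.2% and 9.26% (8.75 to 9.78). The E14_EP order depended on the clusters counted, at 24.2%, 38.9% and 30.8% with the shallow cluster 15 added and with a Good minus Bad difference of -0.813 points after centring within library sets. The intervals are exact binomial ones and cover counting error only. Formative-epiblast-like cells made up 1.52%, 8.98% and 11.4% of CellTag Good, Average and Bad cells and 5.38%, 5.47% and 4.48% of E14_EP cells. The 2C-like share was 0.793%, 1.65% and 2.85% in the CellTag set and 4.63%, 3.30% and 3.68% in the E14_EP set. Exact permutation p was 0.889, 0.278 and 0.611 for these classes (adjusted p = 0.889, 0.556 and 0.889). Blood-like cells numbered 1, 41 and 120 in the CellTag Good, Average and Bad libraries and 14, 0 and 10 in the E14_EP libraries, where 0 of 11212 cells allows a share of up to 0.0268% (exact permutation p = 0.222, adjusted p = 0.556). The CellTag Average and Bad cells of this cluster had 1039 and 3142 Hba-x UMIs, or 87.5% and 76.4% of those in their libraries, and 428 and 1628 Hbb-bh1 UMIs, or 88.8% and 81.3%. Of the other Hba-x UMIs of the CellTag Bad library, 337 were in cluster 4, 347 in the unnamed cluster 11 and 169 in cluster 8. The E14_EP Good and Bad cells had 0 Hba-x UMIs, and 7 and 0 Hbb-bh1 UMIs, so their name rests on the cluster and not on their globin counts. Cluster 8 held 7.24%, 15.6% and 9.41% of CellTag cells and at most 1.08% of an E14_EP library (exact permutation p = 0.833, adjusted p = 0.889).

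**Figure D1:**
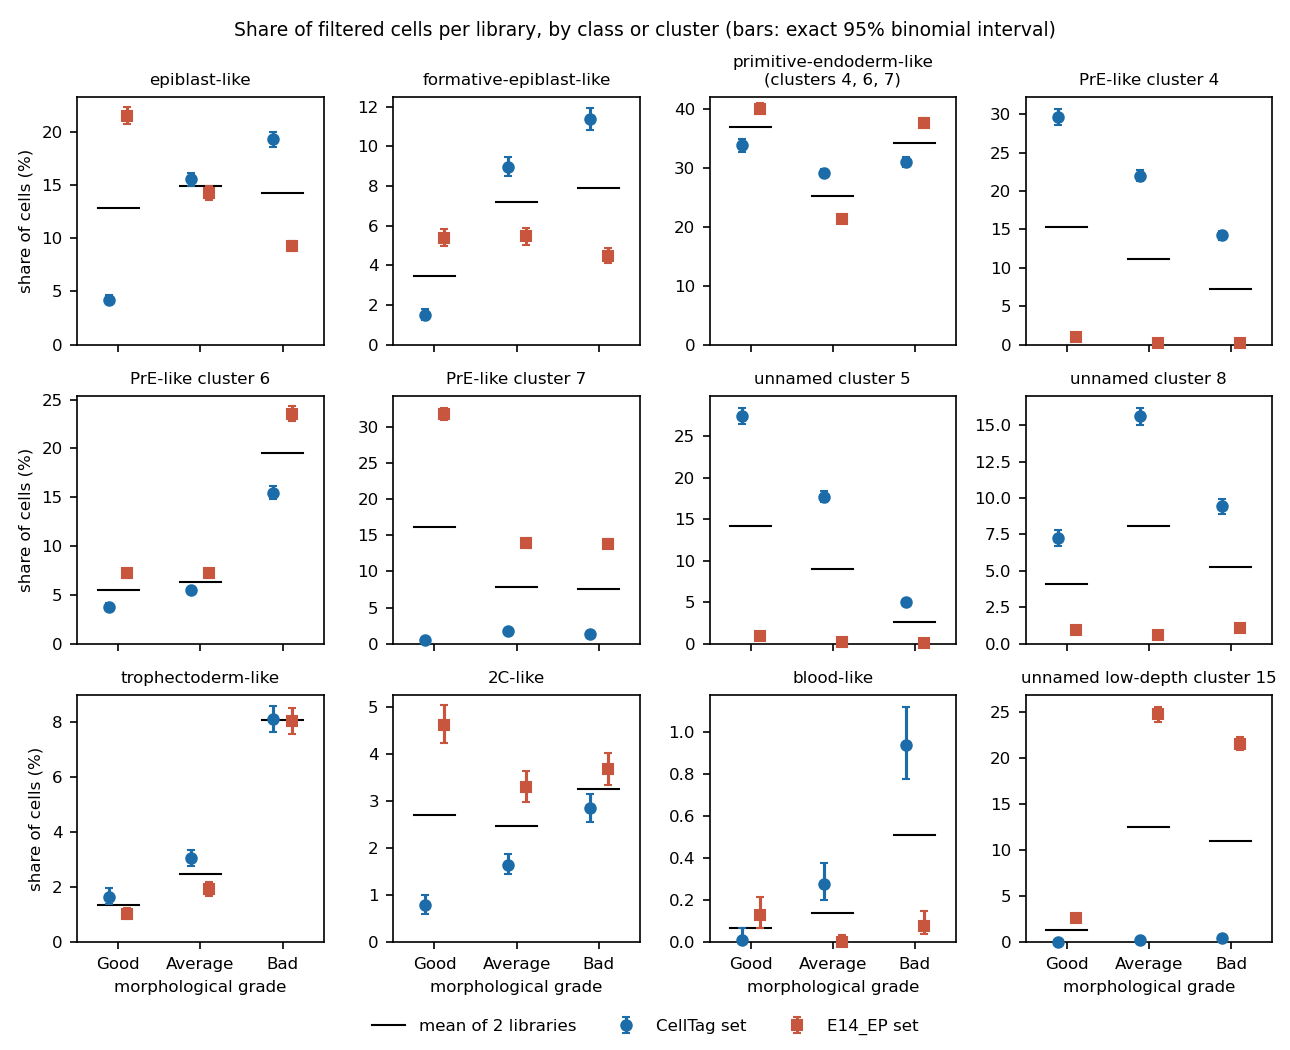
Share of filtered cells in percent (y axis) against grade (x axis) for classes and clusters, with 1 point per library, exact 95% binomial intervals as bars and the mean of 2 libraries as a line. Trophectoderm-like cells are near 8% in both Bad libraries and between 1.03% and 3.04% in the others, while the epiblast-like points of the 2 sets cross.

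In whole libraries, Rbp4 had the largest difference of the named genes higher in Good structures and Gata2 of those higher in Bad ones. Rbp4, which encodes the retinol carrier secreted by visceral endoderm (ENSMUSG00000024990, chromosome 19, 38116629 to 38125281), was 5.43-fold higher in Good, with log2 2.44 ± 0.196 (SE). Its level was 1140 CPM in Good against 277 in Bad in the CellTag set, and 232 against 38.1 in the E14_EP set. Gata2, a transcription factor of trophoblast (ENSMUSG00000015053, chromosome 6, 88193891 to 88207032), was 5.32-fold higher in Bad, at 16.0 CPM ± 5.63 in Good and 90.0 ± 14.7 in Bad (SD, n = 2). Fold changes came from the edgeR fit with TMM factors and library set as a covariate, while CPM were scaled by library totals alone, so a ratio of mean CPM differs from the fold. Of 18533 genes tested, 46 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 26 higher in Good and 20 higher in Bad.

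The other named genes higher in Good were Myl3, a myosin light chain (log2 2.38 ± 0.269 SE), the transcriptional coactivator Cited1 (1.81 ± 0.212) and the VEGF receptor gene Flt1 (1.66 ± 0.138). Prss12 and Lect2, which encode secreted proteins, had log2 changes of 1.58 and 1.32. The imprinted gene Ndn had 1.28, and Ctsh, encoding the lysosomal protease cathepsin H, had 1.20. Acot1 (1.17), Eva1b (1.12), Tnfrsf12a (0.98) and Aldh7a1 (0.94) completed the group. Acot1 has close paralogs, so its reads can be split. Cited1 had 1160 CPM ± 680 in Good and 331 ± 118 in Bad (SD, n = 2), and its set values were log2 1.98 and 1.45.

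Among the genes higher in Bad, Rhox9, an X-linked homeobox gene of trophoblast with the near-identical neighbour Rhox6, had log2 -1.99 ± 0.1996 (SE). The tight junction gene Cldn4 (ENSMUSG00000047501, chromosome 5, 134945119 to 134946934) was at 9.51 CPM ± 0.502 in Good and 33.2 ± 0.294 in Bad (SD, n = 2), with a fitted difference of 3.24-fold. Glipr2 (-1.62), the secreted inhibitor gene Wfdc2 (-1.55), Itm2a (-1.51) and Anxa2 (-1.36) followed. Further down were the transcription factor genes Cebpb (-1.30) and Tfec (-1.14) and the hexokinase gene Hk2 (-0.91). All 23 genes taken by the rule had the same direction in both sets, as the rule requires, and adjusted p in edgeR lay between 0.0322 and 0.0470.

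The count depended on the model and the cells. It was 841 with DESeq2, 20 with upper-quartile factors (7 higher and 13 lower), 8 with at least 3000 UMIs per cell and 0 without library set as a covariate (942 genes at an unadjusted p under 0.05) or with cells of named classes alone (2847 genes). It was 723, 73 and 334 without the CellTag Good, Average or Bad library and 2305, 73 and 1899 without the E14_EP ones.

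**Figure D2:**
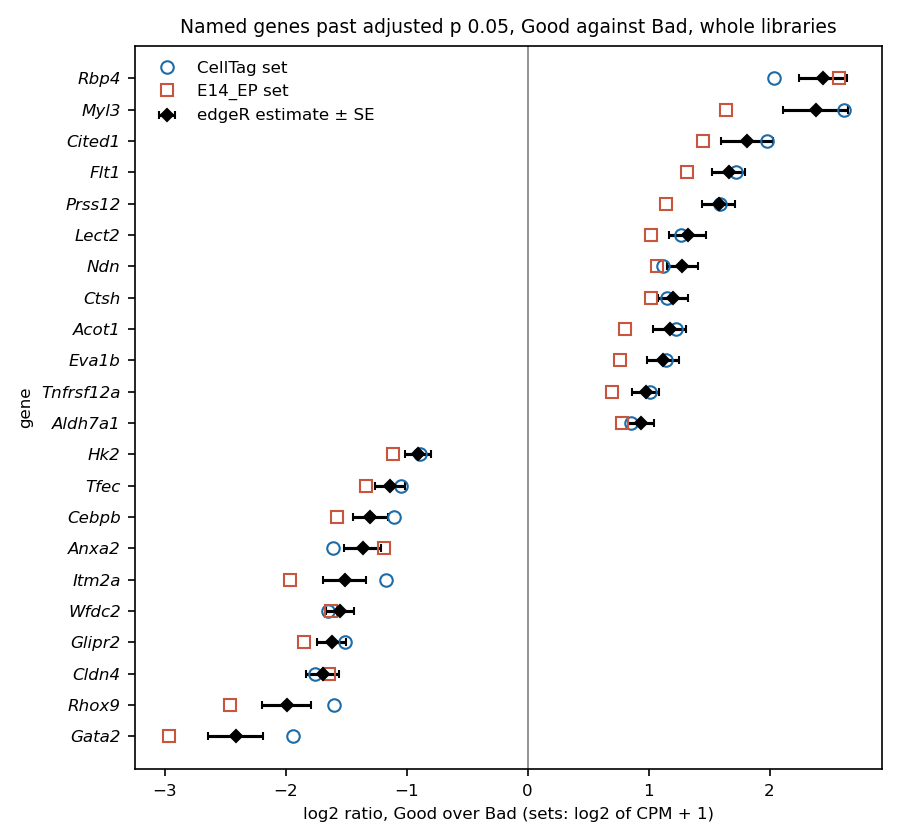
Log2 ratio of Good over Bad (x axis) for the named genes (y axis), with the edgeR estimate and its SE in black and the ratio in each library set as open symbols. All points of a gene lie on the same side of 0, from Rbp4 at 2.44 to Gata2 at -2.41.

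Of the 28 gene lists, 7 passed between Good and Bad with a preset correlation of 0.01, and 0 with an estimated correlation or with fry (smallest adjusted p 0.771 and 0.530, with 0 and 1 lists at an unadjusted p under 0.05). The trophectoderm list had 20 of 22 members lower in Good, with a median log2 of -0.92 (adjusted p = 1.05e-15, and adjusted p = 0.771 with an estimated correlation). Of its members 4 fell over all genes tested, among them Cldn4, Gata2 and Rhox9, and 11 fell and 1 rose when adjusted over the list alone. The member that rose was Cdx2, an early trophectoderm factor that is also a Wnt target, with log2 1.52 ± 0.192 (SE; adjusted p = 0.0540 over all genes). It was at 35.7 CPM in Good and 11.8 in Bad of the CellTag set, and 12.4 and 5.32 in the E14_EP set. The primitive endoderm list had 18 of 24 members higher in Good (adjusted p = 5.27e-06, and adjusted p = 0.771 with an estimated correlation), and its median log2 ratio was 0.73 in the CellTag set and -0.23 in the E14_EP set. Rbp4 passed over all genes, and 5 members rose and 1 fell adjusted over the list alone. Among those that rose were Ttr, a thyroid hormone carrier gene (log2 1.72 ± 0.312 SE), Apob (0.68 ± 0.127) and Plat (1.49 ± 0.300), and the member that fell was the endocytic receptor gene Cubn (-0.53 ± 0.122), named here after its values were seen.

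FGF-ERK target genes were lower in Good for 11 of 13 members, with a median of -0.67 (adjusted p = 0.0023, and adjusted p = 0.771 with an estimated correlation). Over all genes 0 passed in edgeR (6 at an unadjusted p under 0.05) and 3 in DESeq2, while 3 fell in edgeR adjusted over the list alone. Spry2, a feedback inhibitor of the pathway, had log2 -0.87 ± 0.143, Dusp4 -0.996 ± 0.241 and the effector gene Etv5 -0.78 ± 0.204 (SE). The blood list was lower in Good for 6 of 6 members (adjusted p = 4.95e-06, and adjusted p = 0.771 with an estimated correlation). Hba-x, an embryonic globin gene, was at 0.01, 9.06 and 30.71 CPM in CellTag Good, Average and Bad and at most 0.07 CPM in an E14_EP library. It fell over all genes, and Hba-x and Hbb-y fell adjusted over the list alone. Hbb-bh1 was at 3.68 and 14.94 CPM in CellTag Average and Bad and at most 0.05 CPM in the other libraries. All 14 members of the 2C-like list were lower in Good (adjusted p = 0.0023, and adjusted p = 0.771 with an estimated correlation), and 0 passed in edgeR over all genes or adjusted over the list alone (2 at an unadjusted p under 0.05, and 0 in DESeq2). The median log2 ratio of the 2C-like list was -0.61 in the CellTag set and -0.07 in the E14_EP set, with 9 of 14 members of the same sign in both. Without the E14_EP Good or the E14_EP Bad library 12 and 13 lists passed.

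Both epiblast lists passed with opposite medians in the sets. Naive pluripotency genes were lower in Good for 17 of 20 members (adjusted p = 0.0371, and adjusted p = 0.771 with an estimated correlation). Their median log2 ratio was -1.32 in the CellTag set and 0.31 in the E14_EP set. Esrrb had -1.75 and -0.27, and Nanog -1.77 and 0.08. In edgeR 0 naive genes passed over all genes or adjusted over the list alone, with 0 at an unadjusted p under 0.05 and 0 in DESeq2. Formative genes were lower for 8 of 8 (adjusted p = 0.0399, and adjusted p = 0.771 with an estimated correlation), with medians of -0.98 and 0.16. Dnmt3b, a DNA methyltransferase gene, fell by 0.51 ± 0.127 (SE) in edgeR, with an adjusted p = 0.0499 when adjusted over the list alone.

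The other 21 lists did not pass (adjusted p between 0.0615 and 0.897), and single members of some did when adjusted over the list alone. Of the differentiated trophoblast genes only 3 were measured, of which Flt1 rose and Gcm1, a syncytiotrophoblast factor gene (-1.89), fell over all genes. Of the epithelial junction genes, 7 rose and 3 fell adjusted over the list alone, with Cldn7 at 0.91, Cldn6 at 0.91 and Ocln at 1.02 beside Cldn4 at -1.69. Among imprinted genes 4 rose and 5 fell in this way, with Meg3 at 0.70, Rian at 0.73 and Slc38a4 at -1.39. BMP target genes had 3 that fell, Smad7 (-0.76), Gata3 (-1.38) and Id4 (-0.94). Canonical Wnt targets had 3 that rose and 1 that fell, with Sp5 at 1.11, Sp8 at 1.47 and Lgr5 at -1.93, and the list's median of -0.07 was opposite in sign to its mean of 0.05 and its test. In the hypoxia and glycolysis list, with a median of 0.01 (-0.04 with upper-quartile factors) against a mean of -0.11 and a test toward Bad, the prolyl hydroxylase genes P4ha1 (0.95) and P4ha2 (-0.93) had opposite directions and Hk2 fell.

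The heat shock genes Hspa1a (-1.51) and Hspa1b (-1.21), which share near-identical sequence, fell adjusted over the list alone. Of the mesoderm genes Hand1 fell (-2.77) in the same way, and Smad7 fell among Nodal-Activin targets. Among the amino acid stress genes Phgdh rose (0.72) and Atf4 fell (-0.44). Gins2 (0.58) in the S phase list, Hist1h2bc (0.73) among core histones and Cdx2 among Hippo-YAP targets were single members that rose. In the definitive endoderm, neural, germ cell, fibroblast, basement membrane, p53, cholesterol synthesis, and G2 and M phase lists 0 members passed in edgeR adjusted over the list alone, with between 1 and 5 per list at an unadjusted p under 0.05. In DESeq2 1 definitive endoderm, 3 basement membrane and 2 cholesterol synthesis genes passed in this way, and 0 in the other 5 lists. Medians of the cell cycle lists were 0.02 for S phase, or -0.04 with upper-quartile factors, and 0.09 for G2 and M phase (adjusted p = 0.442 and 0.197).

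**Figure D3:**
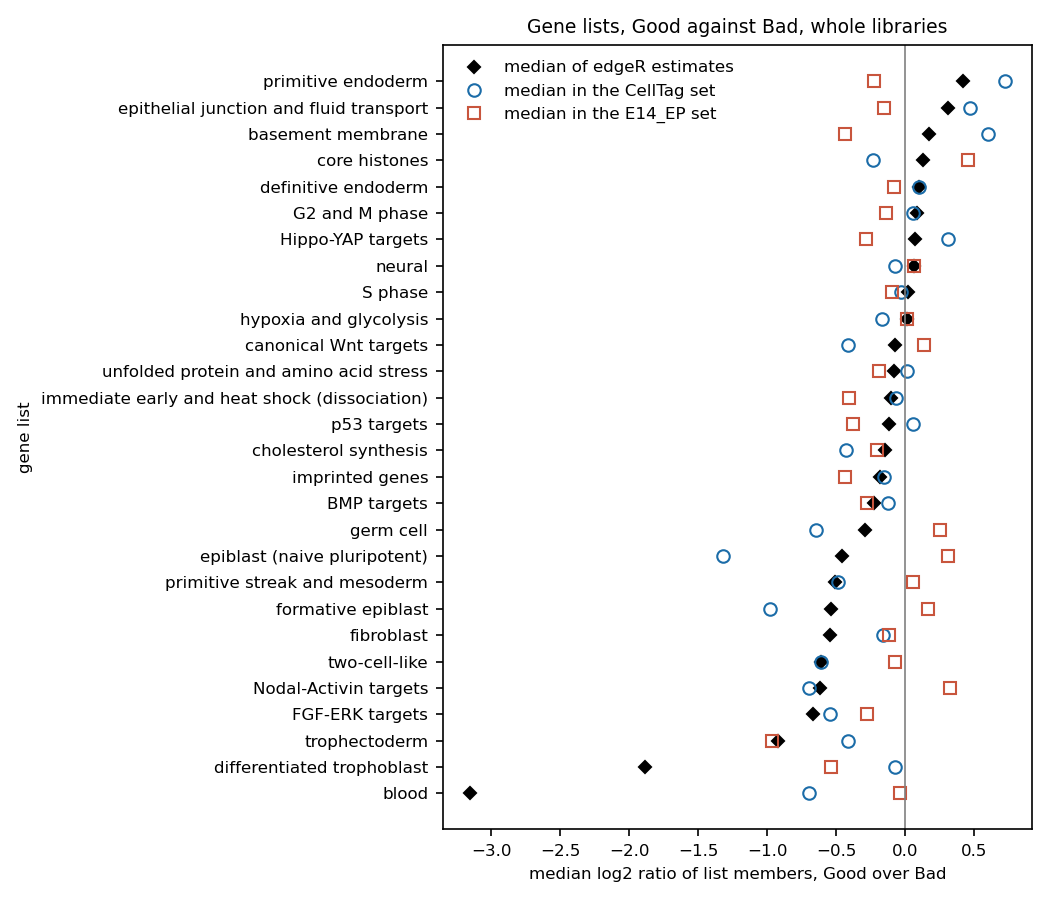
Median log2 ratio of Good over Bad (x axis) of the measured members of each of 28 gene lists (y axis), from the edgeR estimates and within each library set. The trophectoderm medians are below 0 in both sets, and the naive epiblast medians lie at -1.32 and 0.31.

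Between Average and Bad, genes toward Bad with the smallest p included Glipr2 and Tfec, leading genes of cluster 6, and 0 genes passed in edgeR (596 at an unadjusted p under 0.05), against 51 in DESeq2. Glipr2 had log2 -1.26 ± 0.121 (SE), Tfec -1.09 ± 0.123, P4ha2 -0.88 ± 0.129, Pdlim4 -0.89 ± 0.131, Wfdc2 -0.75 ± 0.114 and Cldn4 -0.85 ± 0.130. On the other side Flt1 had 0.85 ± 0.136, Apob 0.75 ± 0.127, Rbp4 0.88 ± 0.187, Ctsh 0.53 ± 0.121, Cyp26a1 0.71 ± 0.171 and Selenop 0.74 ± 0.183. Adjusted p lay between 0.579 and 0.9999 for these. Of the lists, 4 passed at the preset correlation, with adjusted p = 0.817 with an estimated correlation for each of them. The trophectoderm list had 19 of 22 members lower in Average (median -0.62, adjusted p = 2.61e-23). Canonical Wnt targets had 14 of 16 members higher (median 0.32, adjusted p = 7.83e-05), neural genes 8 of 8 higher (adjusted p = 0.0030) and blood genes 5 of 6 lower (adjusted p = 0.0030). Only 4 of 8 neural and 3 of 6 blood genes had the same sign in both sets. In edgeR 0 members of either list passed adjusted over the list alone (1 per list at an unadjusted p under 0.05). Adjusted over the list alone, 6 trophectoderm genes fell and 1 rose, and 3 Wnt targets, Sp5, Sp8 and Cdx2, rose and 2 fell. Median and mean differed in sign for the primitive endoderm list (-0.08 and 0.02), the epithelial list (0.06 and -0.01) and the imprinted list (0.09 and -0.05), none of which passed. Without the CellTag Good, CellTag Bad, E14_EP Good or E14_EP Bad library edgeR called 61, 129, 81 and 58 genes, and 9, 13, 10 and 15 lists passed, with 8 without the E14_EP Average library.

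Between Good and Average, Rbp4 was again first, with log2 1.56 ± 0.190 (SE; adjusted p = 0.346). In edgeR 0 genes passed (2147 at an unadjusted p under 0.05), against 214 in DESeq2. The carbonic anhydrase gene Car4 had 1.06 ± 0.155, Arl6ip5 0.81 ± 0.119, Tnfrsf12a 0.76 ± 0.113, Palm3 0.79 ± 0.117 and Lect2 1.01 ± 0.151. Toward Average, Wfdc2 had -0.81 ± 0.114, Hk2 -0.70 ± 0.107, Gsdme -0.79 ± 0.141, Dancr -0.91 ± 0.177, Slc20a1 -0.57 ± 0.115 and Etv5 -0.99 ± 0.203. Of the lists, 12 passed at the preset correlation, with adjusted p = 0.724 with an estimated correlation for all but basement membrane (0.738). Primitive endoderm genes were higher in Good for 21 of 24 (adjusted p = 2.52e-08) and basement membrane genes for 9 of 12 (adjusted p = 0.0436). The basement membrane median was 0.51 in the CellTag set and -0.31 in the E14_EP set, with 3 of 12 members of the same sign in both. G2 and M phase genes had a median of 0.14, with 18 of 20 above 0 (adjusted p = 0.0074), and set medians of 0.18 and 0.0024, with 10 of 20 members of the same sign in both. Naive epiblast genes were lower for 19 of 20, formative genes for 8 of 8 and FGF-ERK targets for 12 of 13 (adjusted p = 7.02e-05 for each). The trophectoderm, mesoderm, 2C-like, blood, Nodal-Activin and cholesterol synthesis lists were also lower. Adjusted over the list alone, 4 trophectoderm genes fell, as did the FGF-ERK targets Etv5 and Spry2 and the blood genes Hba-x and Hbb-y. Rbp4 rose in the primitive endoderm list, 1 Nodal-Activin target rose and 1, Smad7, fell, and 0 members passed in the naive epiblast, formative, mesoderm, 2C-like, basement membrane, and G2 and M phase lists in edgeR (between 1 and 3 per list at an unadjusted p under 0.05), while DESeq2 called 3 formative genes and 1 basement membrane gene in this way. The hypoxia list had a median of 0.10 against a mean of -0.01, and the unfolded protein list a median of -0.10 and a mean of -0.06 against a test toward Good, and neither passed. Without the CellTag Good, CellTag Bad, E14_EP Good or E14_EP Bad library edgeR called 54, 664, 1810 and 809 genes. Without the CellTag Good or the CellTag Average library 6 and 4 lists passed.

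Within primitive-endoderm-like cells, 911 of 15024 genes passed between Good and Bad, 370 higher in Good and 541 higher in Bad (edgeR). This class had at least 2400 cells per library, against minima between 63 and 335 in the other 4 classes tested, so the counts do not rank the classes. Rbp4 (log2 2.13 ± 0.331 SE), Cdx2 (2.04 ± 0.162), Igfbp1 (2.02 ± 0.225), Pitx1 (1.94 ± 0.294), Myl3 (1.86 ± 0.173) and Acot1 (1.72 ± 0.199) were higher in Good. Higher in Bad were Stmn2, a tubulin-binding protein gene (-2.98 ± 0.276), Ckb (-2.43 ± 0.251), Bcat1 (-2.27 ± 0.184), Marcks (-2.26 ± 0.179), Gng2 (-2.05 ± 0.234) and Glipr2 (-2.02 ± 0.184). Igfbp1, Pitx1 and Myl3 were also leading genes of the unnamed cluster 5, and free RNA was not estimated. Different clusters filled this class. Cluster 4 gave 2353 of the 2686 CellTag Good cells and cluster 7 gave 3492 of the 4390 E14_EP Good cells. Cluster 6 gave 1981 of the 3965 CellTag Bad cells and 2952 of the 4709 E14_EP Bad cells. In cluster 6 alone, whose cells are part of the class, 9 genes passed, 8 of them among the 911. Of the 801 genes called in the class and tested in cluster 6, 746 had the same direction there, at a median ratio of 0.437 to the class difference. Since the class contains these cells, agreement in direction is partly fixed. Without library set as a covariate 0 passed (1078 genes at an unadjusted p under 0.05), and without the CellTag or E14_EP Good library 4922 and 2270 did.

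Among 2C-like cells 6 of 10941 genes passed in edgeR, 1 higher in Good and 5 higher in Bad, and 3 in DESeq2, all 3 higher in Bad. The pluripotency-associated receptor gene Nr0b1 was the gene higher in Good (log2 1.82 ± 0.235 SE), a call that DESeq2 did not make, and Olfr655 (-2.16 ± 0.210), Gfod2 (-1.73 ± 0.204) and Ptcra (-3.98 ± 0.536) were higher in Bad. Ptcra had -0.52 in the CellTag set and -4.19 in the E14_EP set. The count was 563, 28 and 15 without the CellTag Good, Average or Bad library, 265, 19 and 0 without the E14_EP ones (622 at an unadjusted p under 0.05 for the last), and 0 without library set as a covariate (311 genes). In epiblast-like cells 0 of 14514 genes passed in edgeR (2158 at an unadjusted p under 0.05) and 17 in DESeq2. Egr1 (0.88 ± 0.103 SE), Col4a1 (0.74 ± 0.0919) and Cited1 (1.08 ± 0.176) were among the smallest p toward Good. Spry2 (-0.82 ± 0.0902), H19 (-1.11 ± 0.126), Anxa2 (-1.04 ± 0.122) and Smad7 (-0.84 ± 0.101) were among them toward Bad. Adjusted p was between 0.0613 and 0.119 for these, and 1228, 159 and 473 genes passed without the CellTag Good, CellTag Bad or E14_EP Good library. In trophectoderm-like cells 0 of 10518 passed in edgeR (1266 at an unadjusted p under 0.05) and 8 in DESeq2. There the trophoblast factor gene Ascl2 had 1.27 ± 0.168 and the hexokinase gene Hk2 -0.97 ± 0.144 (SE; adjusted p = 0.0593 for both). The count there was 237, 13 and 119 without the CellTag Good, Average or Bad library and 476, 24 and 138 without the E14_EP ones. In formative-epiblast-like cells 0 of 13061 passed in edgeR (1194 at an unadjusted p under 0.05) and 5 in DESeq2, with Cubn at -1.64 ± 0.203 (SE; adjusted p = 0.377), and 32, 3, 15 and 2 genes passed without the CellTag Good, Average or Bad or the E14_EP Bad library.

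More genes passed between the library sets than between grades, with 3 libraries on each side for the sets and 2 for the grades. Between CellTag and E14_EP, 3312 of 18533 genes passed, 1641 higher in CellTag and 1671 higher in E14_EP (edgeR, grade as a covariate). The first principal component of the 6 libraries held 60.6% of the variance and separated the sets, but it also spread the CellTag grades. CellTag Good, Average and Bad lay at -84.8, -37.6 and -14.2 on it, and the E14_EP libraries at 31.9, 57.1 and 47.7. Epiblast-like cells came mainly from cluster 0 in the CellTag set and from cluster 13 in the E14_EP set, and visceral-type endoderm from cluster 4 and cluster 7. Clusters 5 and 8 were mostly of the CellTag set. Cells of named classes alone gave 1698 genes. Without an Average library the count was 442 (CellTag) or 407 (E14_EP), and without a Bad library it was 5637 or 5924.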

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

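The test that counted cluster 15 as epiblast-like was chosen only after the result was seen, while the test on summed counts was fixed before its values were known. Among shares with intervals apart in both sets and lists that passed, Good minus Bad had opposite signs in the library sets for the 6 measures given here, and with 1 library per grade in each set the difference between the sets was not tested. For the epiblast-like share it was -15.05 percentage points in the CellTag set and 12.25 in the E14_EP set. The formative-epiblast-like share differed by -9.85 and 0.902 points, and the 2C-like share by -2.06 and 0.952. Median log2 ratios of Good over Bad were -1.32 and 0.31 for the naive epiblast list, -0.98 and 0.16 for the formative list and 0.73 and -0.23 for the primitive endoderm list. The blood-like share, with few cells, had -0.925 and 0.0478 points, and 14 of the lists that did not pass also had set medians of opposite sign.

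For the epiblast pattern, the summed level of the 20 naive genes over all cells uses no clusters. Its log2 ratio of Good over Bad was -1.49 in the CellTag set and 0.398 in the E14_EP set, so the bound written in advance against naming was met. The opposite signs of this sum do not depend on the naming of clusters. The sum is weighted by UMIs, however, so shallow cells such as those of cluster 15 (median 1979 UMIs) enter it little. It therefore does not decide whether naming caused the opposite shares of cells. The size of the E14_EP difference did depend on the clustering, at 1.09 points at resolution 2 and -0.813 after centring within library sets. Counting the shallow cluster 15, in which 15 of 20 naive genes were raised, turned the E14_EP difference from 12.25 to -6.58 points and left the CellTag one at -15.5, so the criterion written for this explanation was met. Since the summed level goes the other way, shallow epiblast cells and a difference between the sets cannot be told apart, and the reading of this test was changed from met to open after both values had been seen. A biological difference between the sets, whose nature the labels do not give, was not tested.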

How the results depend on the processing

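Robust estimation of the prior, the filter of 3000 UMIs per cell for gene counts, Scrublet's automatic threshold, cells of named classes alone, naming by marker counts alone, cluster 15 and cluster 6 alone were chosen only after the result was seen. Genes called between Good and Bad, 46 in edgeR, numbered 841 with DESeq2, 20 with upper-quartile factors, 412 without a filter on low counts, 78 with all deposited barcodes, 27 with doublets kept, 8 with at least 3000 UMIs and 0 with named classes alone, while robust estimation gave 47, all 46 among them. Of the 46, DESeq2 also called 45, upper-quartile factors 20, all barcodes 45 and doublets kept 27. Between Average and Bad DESeq2 gave 51, between Good and Average DESeq2 gave 214 and no filter 3, and between the sets named classes alone gave 1698. Without the replicate block, that is without pairing libraries by set, 0 genes passed between Good and Bad in whole libraries. Within classes 0 passed in 2C-like and 0 in primitive-endoderm-like cells. The block moved no other count by over 1.5 times. Between the sets, 2218 genes passed without a covariate, against 3312 with grade as one. An estimated correlation and fry each left 0 lists in all 3 comparisons of grades. None of the 23 named genes turned its direction under any alternative run. The rule takes only genes with the same direction in both sets, so a turn was unlikely from the start. Past the threshold, 23 stayed with DESeq2, without a filter and with all barcodes, 21 with Scrublet's threshold and 13 with doublets kept. With upper-quartile factors 11 stayed, with at least 3000 UMIs 5, and without the block or with named classes alone 0. The cause was not tested.

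Within classes, DESeq2 called 3 genes in 2C-like, 17 in epiblast-like, 5 in formative-epiblast-like and 8 in trophectoderm-like cells. No filter gave 147, 460, 110 and 237 there and 2036 in primitive-endoderm-like cells, where cluster 6 alone gave 9. At Leiden resolution 2 the counts were 3 in epiblast-like and 22 in trophectoderm-like cells. Good minus Bad of the primitive-endoderm-like share was 14.62 points at resolution 0.5, 3.76 at resolution 2, -2.82 after centring, -3.92 with doublets kept, 14.26 by marker counts alone, 1.70 at 3000 UMIs and 0.426 at up to 10% mitochondrial UMIs. For the trophectoderm-like share it was -8.26, -9.47, -9.82, -7.86 and -7.81 at resolution 2, after centring, with doublets kept, by marker counts alone and at 3000 UMIs. The cause was not tested. Resolution 0.5 named no formative cluster, and clusters 5 and 8 were not followed into the other clusterings, although some of those hold unnamed clusters with several of the same leading genes.

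Leaving out each library in turn, with the lone library of a grade assumed to vary like the others, gave between 73 and 2305 genes for Good against Bad, 0 and 129 for Average against Bad, 0 and 1810 for Good against Average, and 407 and 5924 for the sets. Lists numbered 5 to 13, 4 to 15 and 4 to 15. Within classes the range was 0 to 563 (2C-like), 0 to 1228 (epiblast-like), 0 to 32 (formative-epiblast-like), 865 to 4922 (primitive-endoderm-like) and 13 to 476 (trophectoderm-like). Share differences ranged from -15.05 to 12.25 (epiblast-like), -9.85 to 0.902 (formative-epiblast-like), 2.45 to 2.84 (primitive-endoderm-like), -6.98 to -6.44 (trophectoderm-like), -2.06 to 0.952 (2C-like), -0.925 to 0.0478 (blood-like), 0.837 to 22.4 (cluster 5) and -2.17 to -0.12 (cluster 8). Depth limits shares in the E14_EP Average and Bad libraries, where 55.6% and 64.7% of cells had at least 3000 UMIs.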

Other observations

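The test of trophectoderm-like shares at 3000 UMIs was chosen only after the result was seen, as were the fits of cluster 6 alone and of the 46 called genes within classes and the ratios given per library set, while the other tests of explanations were written before their values were known. For the test of fold changes at 3000 UMIs the number of called genes had been seen, but not the folds.

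The 46 genes called between Good and Bad in whole libraries were looked up inside the classes. Primitive-endoderm-like cells held between 31.9% and 51.9% of a library's UMIs, so the sums from which the genes were chosen contain these cells, agreement in direction is partly fixed, and no value expected without a change was computed. With that limit, 45 of 46 had the same direction there, at a median ratio of 0.884 to the whole-library difference. The ratio was 0.448 in 2C-like cells (25 of 27 in the same direction), 0.297 in epiblast-like (37 of 40), 0.211 in formative-epiblast-like (25 of 34) and -0.0255 in trophectoderm-like cells (12 of 28). Within the class 41 passed in primitive-endoderm-like cells and 1 in 2C-like cells (edgeR). In the other 3 classes 0 passed, with 2158, 1194 and 1266 of all genes at an unadjusted p under 0.05 and 17, 5 and 8 called by DESeq2 in epiblast-like, formative-epiblast-like and trophectoderm-like cells. Free RNA was not estimated, and the 41 include the globin gene Hba-x, with 337 UMIs in cluster 4, 29 in cluster 6 and 2 in cluster 7 of the CellTag Bad library.

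In cluster 6, the primitive-endoderm-like cluster with raised Gata6 and laminin genes, the small heat shock gene Cryab (log2 1.16 ± 0.127 SE) and Pga5 (0.97 ± 0.114) were higher in Good. Stmn2 (-1.33 ± 0.153), Shkbp1 (-1.15 ± 0.118), Hk2 (-0.93 ± 0.110) and Marcks (-0.88 ± 0.112) were higher in Bad, with adjusted p between 0.0304 and 0.0388 in edgeR.

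A hypothesis for the genes called in whole libraries is that cluster shares set part of their difference. The Good over Bad difference was predicted from each library's cluster shares with the cluster profiles of the other library set. It had the observed direction for 44 of 46 genes. Its median ratio to the observed one was 0.663, above the 0.5 written in advance (95% bootstrap interval 0.61 to 0.730, which treats genes as independent). The clusters were built from the same cells, and called genes such as Rbp4, Glipr2 and Gata2 are among their leading genes. A change within a lineage that splits it into clusters thus counts as a change of shares, so a high ratio is partly fixed. Clusters with under 20 cells in the other set were left out of the prediction after a first run gave no value. With at least 3000 UMIs per cell the median ratio of the folds was 0.996 (0.993 to 1.005), but the cells left out held at most 10.4% of a library's UMIs and could hardly move a fold of summed counts, so this test decides nothing about shallow barcodes, although the bound written in advance against them was met. Per set the median ratio was 0.800 in CellTag, with 0.739 for the 26 genes higher in Good and 0.880 for the 20 higher in Bad. In E14_EP it was 0.529, with 0.427 (10 of 26 at 0.5 or above) and 0.797 (17 of 20). Clusters 7 and 13 held 31.8% and 20.5% of E14_EP Good cells but at most 1.68% and 0.563% of a CellTag library. Clusters 4 and 5 held 29.6% and 27.4% of CellTag Good cells but at most 1.00% and 0.957% of an E14_EP library. Borrowed profiles of these clusters rest on that small part of the other set. The lower E14_EP ratio for genes higher in Good could come from expression changes within clusters or from poorly matched profiles. These were not told apart, and the difference between the sets was not tested.

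Trophectoderm-like cells were more frequent in Bad in both sets. Among cells with at least 3000 UMIs the Bad over Good ratio of shares was 4.36 in the CellTag set and 8.62 in the E14_EP set. The excess in Bad was therefore not made of barcodes under 3000 UMIs, and the bound written against shallow barcodes was met. Cluster 10 had a median of 8423 UMIs, however, so the filter could hardly change its counts. Shallow cells that fell into unnamed clusters were not addressed, so depth stays open as a cause. For the naming of clusters, the summed level of trophectoderm genes over all cells was compared. Its log2 ratio of Bad over Good was -0.163 in the CellTag set and 1.05 in the E14_EP set. The criterion written in advance for naming as the cause, that the sum is not higher in Bad in both sets, was therefore met. Krt8 and Krt18, which other epithelia also express, made up between 57.3% and 84.9% of that sum, and the median log2 of Good over Bad of the list was -0.41 and -0.97, so naming stays open and the reading was changed to open after these values were seen. Whether morphology and trophectoderm content are linked could not be tested beyond 2 libraries per grade.

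For the difference between library sets, the real split of the 6 libraries called 2218 genes without covariates, 1 of 10 splits called as many, and the highest other split called 0. The 10 splits are too few for a share under 0.05.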
